A study of Sus scrofa with 12 samples.

How the data were processed

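Poly(A) RNA from hippocampus of Göttingen minipigs, a small laboratory breed of pig, was sequenced as paired-end reads on the DNBseq platform. The 12 libraries fall into 3 genotypes of 4 animals each. WT animals carried no transgene. PS1 animals carried a human PSEN1 cDNA with a mutation of familial Alzheimer's disease, and APP/PS1 animals carried in addition a human APP cDNA with the Swedish mutation. The labels' protocols count the animals of each genotype separately, so replicates are separate animals. Replicate numbers follow the order of deposition and do not pair animals across genotypes.

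Reads were aligned with HISAT2 2.1.0 to the pig genome Sscrofa11.1 and counted per gene with HTSeq 0.9.1, and the submitters' own test was DESeq2 2.11.40.6, per the submitters' processing notes. Whether the counting used strand is not given in the sources used here. A human transgene contributes only as far as its reads align to the pig gene. The deposited table is described as TPM by the authors, but its columns sum to between 415667 and 489080, whereas TPM columns share the same sum. The deposited values are FPKM, that is reads scaled by gene length and by the assigned reads of the library. This was checked by searching for a length per gene and a total per library that turn every value into a whole number of reads. A solution within a tolerance of 0.0001 reads was found for all 27593 genes with a value above 0, and the recovered reads made up 99.9% of each library's total. Assigned reads per library ran from 28286905 to 36454389. Names of the gene columns in the file header are exchanged, and the columns were read by their content. The planned test assumed TPM. The same limma test on the log scale was kept for the FPKM values. Rescaling every library to the same sum, which turns FPKM into TPM, was run as an alternative on the same tested genes.

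Of the 31907 genes in the table, 17733 had a symbol in the deposited file and 426 more were named from a table that pairs Ensembl gene identifiers with symbols. The 13048 genes with a value of at least 1 in at least 4 libraries were tested. Of these, 11837 had a symbol and 10914 had coordinates, which were matched by symbol to the RefSeq annotation of Sscrofa11.1. Values were transformed as log2(value + 1) and fitted in limma 3.58.1 under R 4.3.3 with 3 genotype means over all 12 libraries and a mean-variance trend, so that the 3 comparisons share an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. Every fold change is on the log2(value + 1) scale, which understates the change of genes with low values. The values were not rescaled between libraries, since FPKM is already scaled to the depth of each library, and scaling by the median of ratios was an alternative.

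Gene lists of pathways, complexes and cell type markers were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and 27 of the 32 processing alternatives. Of 58 lists, 54 had at least 5 tested members. They were tested with limma's camera, with a preset correlation between genes of 0.01. It asks whether the mean t-statistic of a list's members is higher or lower than that of all other tested genes. Ranks were not used, and lists said to rank higher or lower are those with a higher or lower mean statistic. The adjusted p of camera with a correlation estimated from the data is given beside each call. For APP and PSEN1, exact two-sided permutation tests of 4 against 4 libraries were run on the log2 values. The naming rule took APP and PSEN1, then up to 8 called genes with a symbol in each direction whose group ranges did not overlap. It then took up to 4 called members of each list, or, for a called list with fewer than 2 called members, the 2 members with the smallest p. Where fewer than 10 genes were called, the 10 genes with a symbol and the smallest p were named as values that did not pass. Called genes without a symbol fall outside the rule and were named after their values were seen.

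Overlap between the comparisons against the same WT libraries was set beside 100 simulated pairs of unchanged groups, made from the residuals of the real libraries in random order and with random sign, and beside 6 splits of the WT libraries into pairs. No pair of libraries held identical values, and read counts of libraries of the same genotype differed with a chi-square per gene of 36.0 to 196. The limma step was tested on simulated data with known changes, 66 or 67 genes of 13048 at each size of change, and independent noise per gene. With so many changed genes the adjusted p is easier to pass than in the real data. The recovered shares can therefore overstate what the real comparisons could detect. At a log2 change of 1 it recovered 88.1% of the changed genes for PS1 against WT, 86.6% for APP/PS1 against WT and 88.1% for APP/PS1 against PS1. At a log2 change of 0.5 it recovered 47.8%, 53.7% and 35.8%. Of genes without a change, 12, 9 and 3 were called. The alternatives were other pseudocounts, other filters, other scalings, other variance models, covariates, fits with fewer libraries and limma-voom on the recovered reads. The 5 added after the data were seen were rescaling to the same sum, a covariate for the split by ssc-mir-10390, the fit without the 4 libraries low in it, the fit without the 3 libraries highest in TTR, and limma-voom. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 was used to recover reads and to draw the figures.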

Results

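The study asked how human APP and PSEN1 transgenes alter gene networks of Alzheimer's disease risk in pig brain. Hippocampal poly(A) RNA was measured in 4 WT, 4 PS1 and 4 APP/PS1 minipigs, with 28286905 to 36454389 reads assigned to genes per library. Levels are given in FPKM as mean ± SD with n = 4 animals per genotype, and the error of a log2 fold change is its standard error. Adjusted p-values are from limma unless camera or a permutation test is named.

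The libraries differed in several ways besides genotype. Transcripts of the Y-linked genes ZFY, KDM5D and EIF1AY were present in WT replicate 3 and in PS1 replicates 1, 2 and 3. EIF1AY was at 13.4 in that WT library and at 12.1 to 16.9 in those PS1 libraries. It was at no more than 0.0330 in the other 8, among them all APP/PS1 libraries. The Y chromosome is carried by males, so the genotypes differed in sex, which the sample labels do not give. The small RNA gene ssc-mir-10390 was at 229 to 1893 in PS1 replicates 1 and 2 and APP/PS1 replicates 1 and 2, and at 12375 to 16528 in the other 8 libraries. The choroid plexus transcript TTR reached 74.5 in PS1 replicate 2, 33.7 in WT replicate 4 and 21.5 in PS1 replicate 3. Mitochondrially encoded genes made up 38.6% ± 1.72 of the summed FPKM in WT, 41.6% ± 4.30 in PS1 and 45.7% ± 3.90 in APP/PS1 (SD, n = 4).

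For the endogenous pig genes that correspond to the transgenes no difference between genotypes was detected. APP, the precursor of amyloid beta (ENSSSCG00000012022, chromosome 13, 189434854 to 189716120), was at 334.2 ± 20.2 FPKM in WT, 312.7 ± 35.03 in PS1 and 321.9 ± 34.2 in APP/PS1 (SD, n = 4). PSEN1, the catalytic subunit of gamma-secretase (ENSSSCG00000002340, chromosome 7, 96478179 to 96567884), was at 7.69 ± 1.41, 8.53 ± 1.21 and 7.89 ± 1.51. For APP the log2 fold change was -0.10 for PS1 against WT, -0.06 for APP/PS1 against WT and 0.04 for APP/PS1 against PS1, each with a standard error of 0.10. The exact two-sided permutation p was 0.314, 0.6 and 0.686, where 70 arrangements allow no p below 0.0286. For PSEN1 the log2 fold changes were 0.14, 0.03 and -0.11 with a standard error of 0.14, and the exact permutation p was 0.343, 0.771 and 0.571. The 95% intervals from limma for APP/PS1 against WT were 0.82 to 1.1 fold for APP and 0.825 to 1.27 fold for PSEN1. These differences were within the spread between animals. Reads of the human cDNAs count only as far as they align to the pig genes, so these values check the labels only in part. The sign for APP in APP/PS1 against WT turned under median-of-ratios scaling and limma-voom (log2 fold change 0.10 in each) and quantile normalization (0.02).

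**Figure D1:**
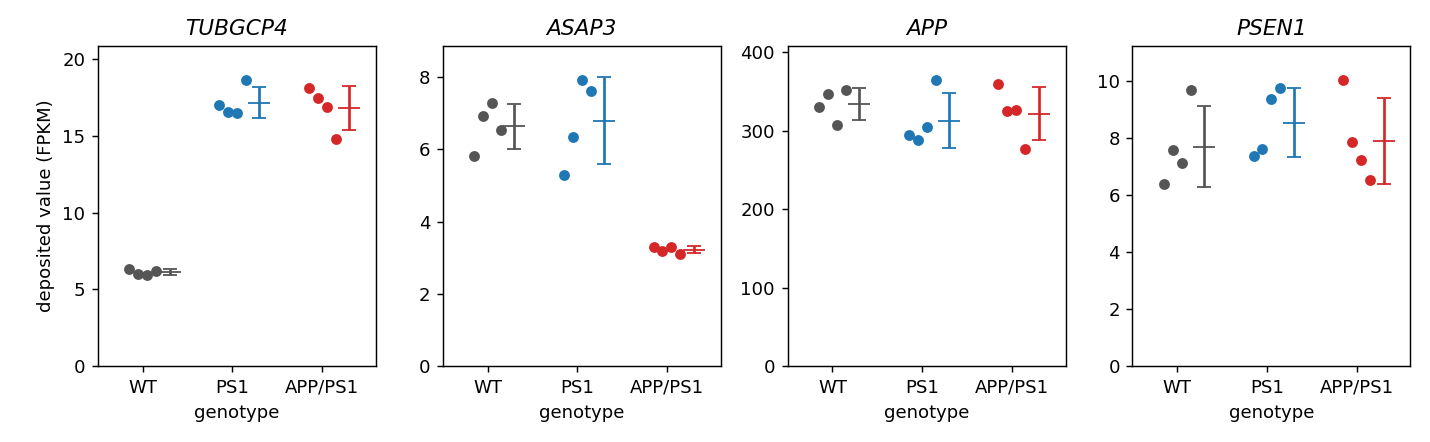
Levels in FPKM of TUBGCP4, ASAP3, APP and PSEN1 in the 4 libraries of each genotype (points), with mean and SD beside them. TUBGCP4 averaged 6.11 in WT, 17.2 in PS1 and 16.8 in APP/PS1, ASAP3 averaged 3.22 in APP/PS1 against 6.64 in WT, and the groups overlap for APP and PSEN1.

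The comparison of PS1 with WT asks what the PSEN1 transgene alone changes. TUBGCP4, a component of the gamma-tubulin complexes that nucleate microtubules, rose from 6.11 ± 0.192 FPKM in WT to 17.2 ± 0.994 in PS1 (SD, n = 4). It rose 2.55-fold on the log2(value + 1) scale, which is less than the ratio of these levels. Its log2 fold change was 1.35 ± 0.07 (adjusted p = 4.95e-06 in limma), and all 4 PS1 libraries lay above all 4 WT libraries. The gene (ENSSSCG00000004708) lies on chromosome 1, 128029393 to 128084039. The unnamed gene ENSSSCG00000038107, chosen after its values were seen, rose from 0.485 ± 0.190 to 9.13 ± 2.57 FPKM, a log2 fold change of 2.75 ± 0.17 (adjusted p = 1.49e-05 in limma). It is a short gene of 480 bases with 4 to 209 reads per library, and the log2(value + 1) scale understates its change. These were the only 2 called genes of 13048, with 2 up and 0 down in limma. limma-voom on recovered reads also gave 2 up and 0 down, and 1068 genes had an unadjusted p under 0.05 where 652 are expected by chance.

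TP53BP1, a protein of the DNA damage response, overlaps TUBGCP4 by 2978 bases at its end (ENSSSCG00000031949, chromosome 1, 127958500 to 128032370). It was at 11.8 ± 1.30 FPKM in WT, 17.1 ± 0.747 in PS1 and 15.2 ± 2.09 in APP/PS1 and did not pass (log2 fold change 0.51 ± 0.10, adjusted p = 0.305 in limma for PS1 against WT). The genes lie on opposite strands, and since counting by strand is not stated, reads in their overlap cannot be told apart. Among the 10 genes with the smallest p in PS1 against WT, the others that did not pass had adjusted p from 0.118 to 0.305 in limma. Lower in PS1 were ANGPTL2, a secreted angiopoietin-like protein, at 1.99 ± 0.490 against 4.96 ± 1.29, ASL, an enzyme of the urea cycle, at 4.23 ± 0.407 against 7.81 ± 1.36, and LMOD1, an actin-binding protein of smooth muscle, at 0.932 ± 0.222 against 1.93 ± 0.318. ATXN7L2 was at 4.70 ± 0.312 against 7.10 ± 0.611, and PPFIA4 at 15.3 ± 1.40 against 22.7 ± 1.67. Higher were MMP19, a matrix metalloproteinase, at 2.89 ± 0.401 against 1.31 ± 0.359, LY96, a co-receptor for bacterial lipopolysaccharide, at 2.98 ± 0.304 against 1.79 ± 0.274, and TMEM14A at 16.9 ± 1.06 against 12.96 ± 0.633.

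**Figure D2:**
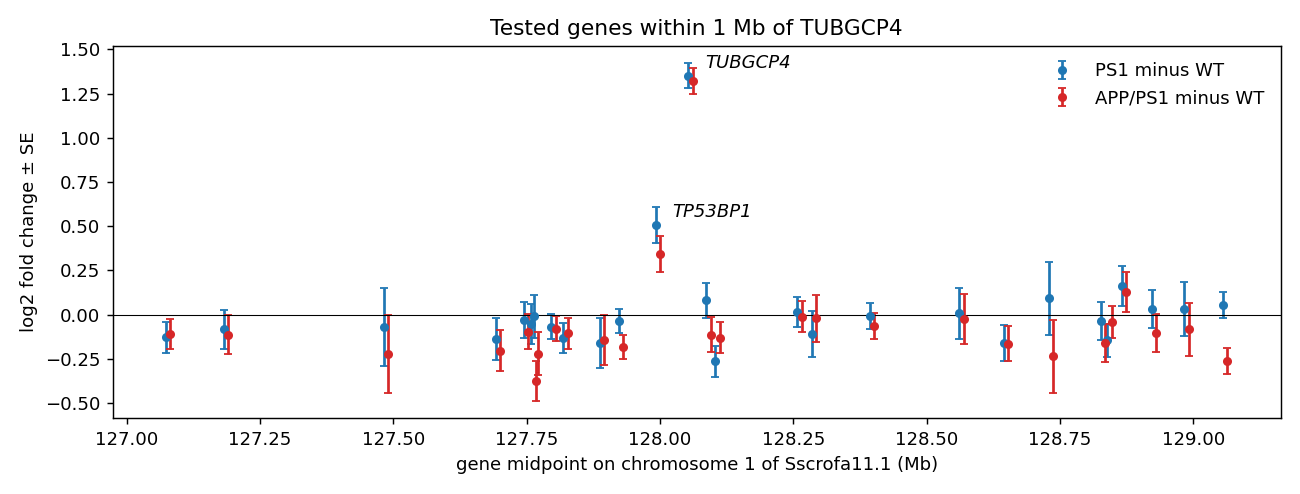
Log2 fold changes against WT, with standard errors, of tested genes within 1 Mb of TUBGCP4, plotted by the gene's midpoint on chromosome 1 of Sscrofa11.1 in Mb for PS1 and APP/PS1. TUBGCP4 stands at 1.35 and 1.32, TP53BP1 at 0.51 and 0.34, and the other 25 genes lie at or below 0.16.

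By camera, 5 of 54 gene lists ranked higher and 4 ranked lower in PS1 than in WT, and 0 held with an estimated correlation, where each had an adjusted p = 0.953. No list member passed limma over all genes. Medians below are those of a list's members minus the median of all tested genes. Counts of members higher or lower are instead taken against a log2 fold change of 0. The median of all tested genes was itself -0.05 in PS1 against WT, so counts of lower members include this shift. Ependymal markers, the cells that line the ventricles, stood 0.32 above all genes with 14 of 14 members higher (adjusted p = 1.32e-05 in camera). CCDC113, a cilium gene, was at 1.68 ± 0.366 FPKM against 1.23 ± 0.126 in WT, and TEKT1 at 1.42 ± 0.415 against 0.825 ± 0.360. Microglia markers stood 0.13 above with 10 of 14 members higher (adjusted p = 7.04e-04 in camera), and homeostatic microglia genes 0.17 above with 12 of 15 higher (adjusted p = 0.00140 in camera). CX3CR1, the fractalkine receptor, was at 26.6 ± 5.22 against 17.1 ± 7.93, and P2RY12, a purinergic receptor, at 8.72 ± 1.124 against 6.23 ± 2.27. SPARC, counted among the homeostatic genes and also made by astrocytes and vessels, went the other way at 403.7 ± 79.5 against 524.5 ± 73.1. Immediate early genes, induced by neuronal activity, stood 0.14 above with 21 of 28 higher (adjusted p = 0.00277 in camera). NR4A3 was at 9.60 ± 1.26 against 7.45 ± 0.793, and CYR61 at 4.97 ± 2.27 against 2.91 ± 0.663.

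Mitochondrially encoded genes stood 0.15 above all genes in PS1, with 9 of 13 higher (adjusted p = 0.00724 in camera, adjusted p = 0.953 with an estimated correlation). Quantile normalization, where the list stood at -0.07, sets the highest values of all libraries equal and so cannot test these genes, which ranked 1 to 17 of all tested genes in level. ND6, a subunit of complex I, was at 7919 ± 1669 FPKM against 5611 ± 592 in WT, and ATP8 at 7798 ± 6667 against 2279 ± 696. ATP8 was at 13895 and 13238 in PS1 replicates 1 and 2, the libraries with low ssc-mir-10390, and at 2016 and 2042 in the others. In the 8 libraries with high ssc-mir-10390 the list stood at -0.02 relative to all genes (adjusted p = 0.780 in camera). Among lists that ranked lower, cholesterol synthesis genes stood at -0.16 with 23 of 26 lower (adjusted p = 0.00110 in camera). DHCR7 was at 10.4 ± 2.07 against 13.9 ± 1.28, and LSS at 12.3 ± 2.41 against 16.2 ± 2.12. Ribosomal protein genes stood at -0.07 with 53 of 58 lower (adjusted p = 7.04e-04 in camera) and included RPL8 at 78.0 ± 4.13 against 92.3 ± 3.35 and RPL18 at 20.5 ± 2.38 against 24.4 ± 0.406. Nuclear genes of oxidative phosphorylation stood at -0.06 with 55 of 61 lower (adjusted p = 7.04e-04 in camera), among them NDUFB11 at 7.62 ± 0.755 against 10.9 ± 1.76 and COX4I1 at 37.0 ± 5.35 against 52.7 ± 7.38. Proteasome subunits stood at -0.03 with 28 of 33 lower (adjusted p = 0.0497 in camera), a call lost in 21 of 32 alternatives. PSMB6 was at 36.1 ± 4.26 against 42.6 ± 3.26, and PSMA5 at 16.7 ± 1.10 against 19.7 ± 1.80. Each of these 9 calls ended with the estimated correlation. Leaving out a library ended calls of the other 8 lists but not the ependymal call. Without WT replicate 1 the adjusted p in camera was 0.0950 for both microglia lists and 0.158 for oxidative phosphorylation and proteasome. Without WT replicate 2 it was 0.162 for cholesterol and 0.133 for immediate early and proteasome genes, and without WT replicate 3 it was 0.121 for ribosomal genes. The mitochondrially encoded call ended without WT replicate 4 (0.188), PS1 replicate 1 (0.0564) or PS1 replicate 2 (0.228), and the cholesterol call also without PS1 replicate 3 (0.246). The immediate early call also ended without PS1 replicate 2 (0.165). The proteasome call ended in addition without WT replicate 4 (0.208), PS1 replicates 1 (0.109) and 2 (0.124) and APP/PS1 replicates 1 (0.0767) and 2 (0.0531).

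The comparison of APP/PS1 with WT adds the APP transgene. Of 13048 genes, 3 rose and 2 fell in limma. TUBGCP4 rose to 16.8 ± 1.43 FPKM (SD, n = 4). On the log2(value + 1) scale it rose 2.499-fold, a log2 fold change of 1.32 ± 0.07 (adjusted p = 6.44e-06 in limma). ENSSSCG00000038107 rose to 6.83 ± 1.32 FPKM, a log2 fold change of 2.39 ± 0.17 (adjusted p = 6.98e-05 in limma). ASAP3, which activates the GTPase of Arf proteins in membrane traffic (ENSSSCG00000028108, chromosome 6, 81309748 to 81360054), fell from 6.64 ± 0.625 FPKM in WT to 3.22 ± 0.101, a log2 fold change of -0.85 ± 0.11 (adjusted p = 0.0172 in limma). The unnamed genes ENSSSCG00000047210 and ENSSSCG00000012427, chosen after their values were seen, changed with log2 fold changes of 1.19 ± 0.17 and -1.39 ± 0.20 (adjusted p = 0.0488 for each in limma). The first was at 0.840 ± 0.151 in WT, 3.12 ± 0.996 in PS1 and 3.23 ± 0.746 in APP/PS1, and the second at 31.4 ± 6.74, 13.5 ± 1.14 and 11.6 ± 3.35. Both stood in PS1 near their level in APP/PS1, although neither was called for PS1 against WT. There the first was called with array weights and after rescaling without mitochondrial genes, among other settings, and the second without APP/PS1 replicate 3.

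The distribution as a whole lay below 0 in this comparison. The median log2 fold change of all tested genes was -0.12, and median-of-ratios scaling moved it to 0.01. Relative to that median the log2 fold change was 1.44 for TUBGCP4, 2.51 for ENSSSCG00000038107, -0.73 for ASAP3, 1.31 for ENSSSCG00000047210 and -1.27 for ENSSSCG00000012427. With that scaling 3 genes were up and 1 was down, since ENSSSCG00000012427 no longer passed. Of 2175 genes with an unadjusted p under 0.05 in limma, 88 were higher and 2087 lower, and with median-of-ratios scaling 375 were higher and 343 lower. The same split was 213 higher and 855 lower for PS1 against WT, which became 421 and 400, and 73 higher and 969 lower for APP/PS1 against PS1, which became 346 and 316. Rescaling every library to the same sum gives TPM, the measure that the planned test assumed. With it 923 genes were called for APP/PS1 against WT, 10 of them up. The median log2 fold change of all tested genes was then -0.25. Array weights gave 285 called genes, 22 of them up. In the 8 libraries with high ssc-mir-10390, 1 gene was called, TUBGCP4. Leaving out a library ended the ASAP3 call for WT replicates 2 and 3 and each APP/PS1 replicate (adjusted p = 0.0519 to 0.0944 in limma), with log2 fold changes from -0.86 to -0.81. The ENSSSCG00000047210 call ended without any of the WT or APP/PS1 libraries or PS1 replicate 4 (highest adjusted p = 0.131), and the ENSSSCG00000012427 call ended in all cases but those without WT replicate 4 or APP/PS1 replicate 3 (highest adjusted p = 0.140 in limma).

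The genes with the next smallest p in APP/PS1 against WT did not pass (adjusted p from 0.0823 to 0.0902 in limma), and all were lower in APP/PS1. With median-of-ratios scaling all stayed lower, at log2 fold changes from -0.84 (ANGPTL2, -0.96 unscaled) to -0.23 (CFAP410, -0.36 unscaled). Their adjusted p in limma then ran from 0.171 (ANGPTL2) to 0.487 (PPP1R12C). ERBB2, a receptor tyrosine kinase, was at 2.61 ± 0.190 FPKM against 3.79 ± 0.282 in WT, and SIRT3, a mitochondrial deacetylase, at 2.94 ± 0.257 against 4.47 ± 0.365. P4HA2, a collagen prolyl hydroxylase, was at 1.34 ± 0.0667 against 2.27 ± 0.189, and ANGPTL2 at 2.02 ± 0.383 against 4.96 ± 1.29. MEGF8 was at 8.29 ± 0.964 against 12.1 ± 0.510, and PPP1R12C, a subunit of myosin phosphatase, at 10.8 ± 0.842 against 15.0 ± 1.10. IAH1 was at 2.65 ± 0.144 against 3.99 ± 0.235, and CFAP410, a cilium gene, at 3.76 ± 0.0966 against 5.11 ± 0.134.

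By camera, 10 of 54 lists ranked higher and 4 ranked lower in APP/PS1 than in WT, and 0 held with an estimated correlation. Mitochondrially encoded genes stood 0.43 above all genes with 12 of 13 higher (adjusted p = 3.77e-20 in camera, adjusted p = 0.0753 with an estimated correlation). None passed over all genes, and 6 passed adjusted over the list alone, or 9 with median-of-ratios scaling. ND5, of complex I, was at 9064 ± 484 FPKM against 6373 ± 701 in WT, and ND6 at 9770 ± 1719 against 5611 ± 592. In the 8 libraries with high ssc-mir-10390 the list stood 0.52 above all genes (adjusted p = 5.21e-15 in camera with the preset correlation). Of APP/PS1 only replicates 3 and 4 are among them, the libraries with the fewest assigned reads. Their mitochondrially encoded shares were 41.0% and 44.6%, where WT replicate 1 had 41.1%. With quantile normalization, which cannot test genes of these top ranks, it stood 0.08 above and was not called (adjusted p = 0.639 in camera). The mean log2 level of the list over the median gene of each library differed by 0.63 between the genotypes, with an exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries allow, and p = 0.771 adjusted over 54 lists. The permutation p in this comparison was 0.114 for ribosomal, 0.257 for oxidative phosphorylation, 0.314 for microglia marker and 0.286 for GABA genes. It was 0.143 for ependymal markers in PS1 against WT and 0.229 for presynaptic vesicle genes in APP/PS1 against PS1. No list had an adjusted permutation p below 0.771 in any comparison.

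Lists that ranked lower in APP/PS1 held genes of translation, energy and splicing. Their counts of lower members are against 0, while the median log2 fold change of all tested genes was itself -0.12. These counts therefore include the shift of all genes. Ribosomal protein genes stood at -0.12 with 57 of 58 lower (adjusted p = 4.03e-09 in camera, adjusted p = 0.638 with an estimated correlation), and 9 passed adjusted over the list alone against 0 over all genes. RPL8 was at 73.6 ± 5.46 FPKM against 92.3 ± 3.35, and RPL13 at 39.6 ± 4.75 against 51.4 ± 1.90. Ribosomal proteins have many pseudogenes, and how reads were shared among the copies is not stated. Nuclear genes of oxidative phosphorylation stood at -0.10 with 59 of 61 lower (adjusted p = 1.39e-08 in camera, adjusted p = 0.638 with an estimated correlation), and 10 passed adjusted over the list alone. NDUFA13 was at 4.56 ± 0.174 against 6.22 ± 0.561, and SDHD, of complex II, at 27.0 ± 2.16 against 33.6 ± 2.46. Proteasome subunits stood at -0.05 (adjusted p = 0.00272 in camera, adjusted p = 0.638 with an estimated correlation), with PSMA5 at 16.0 ± 1.94 against 19.7 ± 1.80 and PSMC5 at 13.4 ± 1.06 against 16.5 ± 1.53. Nuclear and splicing-related transcripts stood at -0.07 (adjusted p = 0.00401 in camera, adjusted p = 0.748 with an estimated correlation), with LUC7L at 9.03 ± 0.236 against 11.5 ± 0.759 and CCNL2 at 15.0 ± 0.811 against 18.4 ± 1.29. With median-of-ratios scaling the proteasome and splicing calls ended, at -0.02 and -0.05 relative to all genes. The ribosomal and oxidative phosphorylation calls held, but 0 members of either passed adjusted over the list alone, with log2 fold changes of -0.17 for RPL8 (-0.32 unscaled), -0.22 for RPL13 (-0.38), -0.24 for NDUFA13 (-0.37) and -0.15 for SDHD (-0.31).

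**Figure D3:**
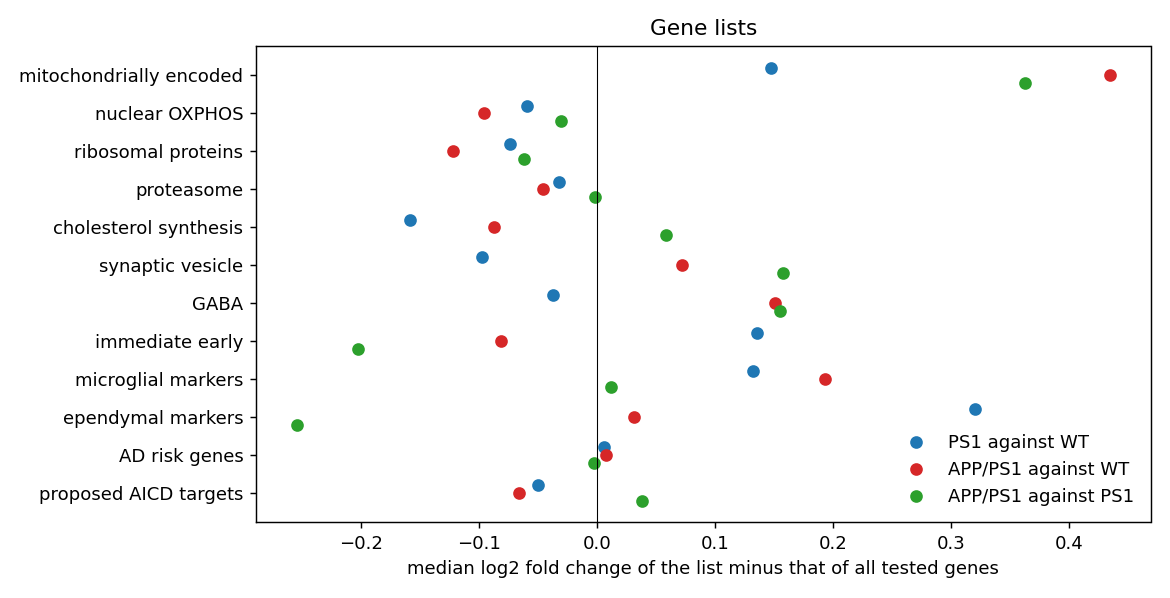
Median log2 fold change of gene lists minus that of all tested genes, for the 3 comparisons. Mitochondrially encoded genes lie at 0.43 for APP/PS1 against WT and 0.36 for APP/PS1 against PS1, and ribosomal protein genes at -0.12 and -0.06.

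Markers of microglia and of synapses ranked higher than other genes in APP/PS1 against WT. Microglia markers stood 0.19 above all genes with 11 of 14 higher (adjusted p = 4.19e-05 in camera, adjusted p = 0.638 with an estimated correlation). P2RY12 was at 7.78 ± 1.16 FPKM against 6.23 ± 2.27, while AIF1 was at 7.45 ± 1.43 against 9.04 ± 1.44. Homeostatic microglia genes stood 0.16 above with 10 of 15 higher (adjusted p = 0.00366 in camera, adjusted p = 0.684 with an estimated correlation), although SPARC was at 359.2 ± 63.5 against 524.5 ± 73.1. GABA and inhibitory synapse genes stood 0.15 above (adjusted p = 0.00122 in camera, adjusted p = 0.638 with an estimated correlation), with GABRA5 at 65.5 ± 13.4 against 54.2 ± 15.9 and GPHN, the gephyrin scaffold, at 7.29 ± 1.08 against 8.28 ± 0.660. Glutamate receptor genes stood 0.08 above (adjusted p = 0.002002), presynaptic vesicle genes 0.07 above (adjusted p = 0.00137) and calcium handling genes 0.08 above (adjusted p = 0.00231 in camera), with an adjusted p = 0.638, 0.684 and 0.638 with an estimated correlation. Their members with the smallest p were lower in APP/PS1: GRIK4 at 6.26 ± 0.929 against 7.86 ± 1.10, NRGN at 677 ± 125 against 782 ± 130, SNCB at 15.0 ± 4.03 against 18.1 ± 2.24, CPLX1 at 61.9 ± 14.9 against 82.5 ± 26.8, ITPR3 at 1.17 ± 0.205 against 1.60 ± 0.371 and CAMK2G at 45.5 ± 9.22 against 54.8 ± 5.57. With median-of-ratios scaling these log2 fold changes shrank, to between -0.22 (CPLX1) and -0.05 (NRGN), from between -0.38 (CPLX1) and -0.21 (NRGN) unscaled.

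Interferon-stimulated genes (0.06 above, adjusted p = 0.0374 in camera, adjusted p = 0.805 with an estimated correlation) included CXCL10 at 2.095 ± 0.449 against 1.04 ± 0.444 and GBP2 at 4.24 ± 0.581 against 5.45 ± 0.678. Neuropeptide and monoamine genes stood 0.03 above (adjusted p = 0.0265 in camera, adjusted p = 0.638 with an estimated correlation), but were not called with limma-voom (adjusted p = 0.983 in camera), with TRH at 0.818 ± 0.522 against 2.04 ± 1.49 and PENK at 15.9 ± 3.19 against 21.6 ± 4.77. Markers of striatum and thalamus stood 0.13 above (adjusted p = 0.00918 in camera, adjusted p = 0.611 with an estimated correlation), with RORA at 2.92 ± 0.195 against 2.53 ± 0.292. PENK, whose levels are given above, is also a member of this list and was lower in APP/PS1. For 5 of the 10 lists that ranked higher, the median log2 fold change itself was below 0, at -0.05 for presynaptic vesicle, -0.04 for glutamate receptor, -0.04 for calcium handling, -0.05 for interferon-stimulated and -0.09 for neuropeptide genes, and the mean was below 0 for these and for the GABA and striatal lists. Their calls reflect members that lay less far below 0 than other genes did. With median-of-ratios scaling 5 lists were called: the mitochondrially encoded, ribosomal, oxidative phosphorylation, microglia marker and GABA lists. Leaving out a library ended 9 of the 14 calls at least once, but none of those of the mitochondrially encoded, ribosomal, oxidative phosphorylation, proteasome and microglia marker lists. Without APP/PS1 replicate 3 the adjusted p in camera was 0.0968 for GABA, 0.0582 for splicing, 0.0613 for interferon and 0.158 for presynaptic vesicle, striatal and neuropeptide genes. The calcium and glutamate receptor calls ended without WT replicate 4 (0.160 and 0.268) or APP/PS1 replicate 4 (0.191 and 0.134). The homeostatic microglia call ended without WT replicate 1 (0.288) or WT replicate 2 (0.108). Without WT replicate 3 the adjusted p was 0.0675 for splicing, 0.342 for neuropeptide and 0.325 for presynaptic vesicle genes. The neuropeptide call also ended without WT replicate 4 (0.122) or APP/PS1 replicate 2 (0.175). In these cases some medians lay below that of all genes: the neuropeptide list stood at -0.11 without WT replicate 3, -0.04 without WT replicate 4, -0.02 without APP/PS1 replicate 2 and -0.13 without APP/PS1 replicate 3. The striatal list stood at -0.04 without APP/PS1 replicate 3 and the presynaptic list at -0.0013 without WT replicate 3. Rescaled to the same sum, the neuropeptide list was called but its median stood at -0.0040. With the filter at 5 it was called at -0.02, and the striatal list stood at -0.04 and was not called. With no filter on low values the calcium, glutamate receptor, presynaptic and interferon lists stood below all genes and were not called. With array weights the interferon and presynaptic lists stood at -0.04 and -0.02 and were not called. The interferon call also ended without WT replicates 1 (0.288) and 4 (0.123), PS1 replicates 1 (0.0517) and 3 (0.0610) and APP/PS1 replicate 1 (0.171).

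Genes at Alzheimer's disease risk loci, the networks the study is about, were called in none of the 3 comparisons. Over 65 tested genes their median stood 0.01 above that of all genes in PS1 against WT (adjusted p = 0.464), 0.01 above in APP/PS1 against WT (adjusted p = 0.107) and -0.0028 relative to it in APP/PS1 against PS1 (adjusted p = 0.546 in camera), and 0 passed in limma adjusted over the list alone. The mean log2 level of the list over the median gene was 0.05 higher in APP/PS1 than in WT, with an exact two-sided permutation p = 0.0286, the smallest possible, and p = 0.771 adjusted over 54 lists. Proposed targets of the APP intracellular domain, 21 tested genes, had an adjusted p = 0.464, 0.947 and 0.322 in camera. Genes of APP cleavage and gamma-secretase, 28 tested, had an adjusted p = 0.849, 0.278 and 0.133 in camera. Of these 28, 1 passed adjusted over the list alone in each comparison against WT, which was APBB3, a binding partner of APP, at 8.18 FPKM in PS1 and 8.14 in APP/PS1 against 10.5 in WT. It did not pass over all genes (adjusted p = 0.347 and 0.105 in limma), nor over the list alone with median-of-ratios scaling.

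The comparison of APP/PS1 with PS1 addresses the APP transgene on the PS1 background. It is confounded with sex, since Y-linked transcripts were present in PS1 replicates 1, 2 and 3 and near 0 in all APP/PS1 libraries. By itself it can hardly tell an effect of APP from one of sex. In limma 0 genes rose and 1 fell, which was ASAP3, at 3.22 ± 0.101 FPKM in APP/PS1 against 6.78 ± 1.20 in PS1 (SD, n = 4). Its log2 fold change was -0.87 ± 0.11 (adjusted p = 0.0418 in limma), with all 4 APP/PS1 libraries below all 4 PS1 libraries, and limma-voom on recovered reads also gave 0 up and 1 down. In all, 1042 genes had an unadjusted p under 0.05. The call was lost on leaving out any library except PS1 replicate 1, with adjusted p from 0.0593 to 0.257 and log2 fold changes from -0.89 to -0.80. It was also lost in the 8 libraries with high ssc-mir-10390 (log2 fold change -1.06, adjusted p = 0.185 in limma). The same held with the Y-linked level as a covariate (log2 fold change -0.87, adjusted p = 0.735 in limma).

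Other genes with small p in APP/PS1 against PS1 did not pass (adjusted p from 0.436 to 0.533 in limma). INPP5F, a phosphoinositide phosphatase (chromosome 14, 129577594 to 129671541), was at 285.6 ± 19.4 FPKM in APP/PS1, 171.4 ± 47.6 in PS1 and 157.3 ± 22.8 in WT. HIST1H1D, a linker histone, was at 8.12 ± 1.87 against 2.78 ± 1.51 in PS1. PRDX3, a mitochondrial peroxiredoxin, was at 56.9 ± 3.85 against 71.7 ± 3.99, CYP4V2 at 6.48 ± 0.511 against 9.50 ± 1.23, and EPHB3, an ephrin receptor, at 0.947 ± 0.216 against 1.88 ± 0.305. ZMYM5 was at 4.74 ± 0.260 against 5.98 ± 0.206, and KLHL42 at 4.53 ± 0.202 against 5.62 ± 0.0575. MIR132, the precursor of a microRNA induced by neuronal activity, was at 0.224 ± 0.154 against 1.63 ± 0.423, which rests on 0 to 7 reads per library. A small RNA of the family RF00016 (ENSSSCG00000018524) was at 1.77 ± 1.16 against 5.32 ± 1.48, from 2 to 24 reads.

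By camera, 10 of 54 lists ranked higher and 5 ranked lower in APP/PS1 than in PS1, and 0 held with an estimated correlation. Counts of higher and lower members are again against 0, while the median log2 fold change of all tested genes was -0.07. With median-of-ratios scaling and limma-voom fewer lists were called, as given below. Of 32 alternatives, 22 ended the call for extracellular matrix genes and 19 for pericyte and smooth muscle markers. The excitatory neuron and unfolded protein calls were each lost in 14, and the presynaptic vesicle, GABA and histone calls each in 2. Mitochondrially encoded genes stood 0.36 above all genes with 13 of 13 higher (adjusted p = 3.54e-11 in camera, adjusted p = 0.280 with an estimated correlation). ND5 was at 9064 ± 484 FPKM against 6794 ± 404 in PS1, and ND3 at 11478 ± 1748 against 9128 ± 714. Presynaptic vesicle genes stood 0.16 above with 24 of 39 higher (adjusted p = 8.68e-06 in camera, adjusted p = 0.792 with an estimated correlation), with STXBP1 at 89.9 ± 16.9 against 70.2 ± 5.17 and RIMS1 at 27.3 ± 5.26 against 35.1 ± 7.22. GABA and inhibitory synapse genes stood 0.16 above (adjusted p = 4.16e-04 in camera, adjusted p = 0.792 with an estimated correlation), with GABBR2 at 61.8 ± 8.35 against 52.2 ± 5.70 and GLRB at 22.0 ± 1.31 against 20.7 ± 0.806. Inhibitory neuron markers stood 0.19 above (adjusted p = 0.00288 in camera, adjusted p = 0.794 with an estimated correlation), with VIP at 4.55 ± 2.43 against 2.99 ± 1.09 and CALB2 at 11.6 ± 15.5 against 4.12 ± 3.0. CALB2 was at 34.7 in APP/PS1 replicate 3 and at 3.41 to 4.47 in the others, and without that library its log2 fold change was 0.07 instead of 0.80. Excitatory neuron markers (adjusted p = 0.0395 in camera, adjusted p = 0.421 with an estimated correlation) included TBR1 at 14.5 ± 8.43 against 7.77 ± 2.08 and SATB2 at 1.75 ± 0.713 against 1.16 ± 0.332. Pan-neuronal markers (adjusted p = 0.0457 in camera, adjusted p = 0.794 with an estimated correlation) included ELAVL3 at 41.9 ± 3.04 against 47.6 ± 4.42 and NEFM at 97.2 ± 23.1 against 113.5 ± 21.3, both lower.

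Histone genes stood 0.16 above with 5 of 7 higher (adjusted p = 0.00288 in camera, adjusted p = 0.280 with an estimated correlation). HIST1H2BD was at 1.57 ± 0.438 FPKM against 1.03 ± 0.380 in PS1. The list mixes replication-dependent histones, whose transcripts mostly lack a poly(A) tail, with variants such as H2AFZ that have one. Neuropeptide genes (adjusted p = 0.0242), extracellular matrix genes (adjusted p = 0.0494) and pericyte and smooth muscle markers (adjusted p = 0.0494 in camera) were also called higher, each with adjusted p = 0.794 with an estimated correlation. PENK was at 15.9 ± 3.19 against 26.2 ± 13.4, SLC18A2 at 2.38 ± 0.307 against 2.74 ± 0.285, HAPLN1 at 3.49 ± 0.462 against 4.23 ± 0.700, TNC at 1.06 ± 0.461 against 1.59 ± 0.351, NOTCH3 at 4.63 ± 0.626 against 5.22 ± 0.680 and TAGLN at 6.53 ± 5.79 against 3.65 ± 1.25. TAGLN was at 15.2 in APP/PS1 replicate 2 and at 3.39 to 4.06 in the others, and without that library its log2 fold change was 0.03 instead of 0.48. The mean of the matrix list was -0.00065 although its median was 0.0038. Among lists that ranked lower, ependymal markers stood at -0.25 with 14 of 14 lower (adjusted p = 0.0176 in camera, adjusted p = 0.794 with an estimated correlation), with TEKT1 at 0.781 ± 0.377 against 1.42 ± 0.415 and RSPH4A at 1.49 ± 1.20 against 2.69 ± 0.953. Immediate early genes stood at -0.20 with 26 of 28 lower (adjusted p = 0.00850 in camera, adjusted p = 0.794 with an estimated correlation), with NR4A3 at 7.06 ± 0.695 against 9.60 ± 1.26 and SIK1 at 4.90 ± 1.06 against 9.84 ± 3.01. Genes of the unfolded protein response stood at -0.05 (adjusted p = 0.0457 in camera, adjusted p = 0.794 with an estimated correlation), with MANF at 12.4 ± 0.930 against 15.5 ± 1.56 and HSPA5 at 72.9 ± 8.21 against 86.9 ± 6.31. Splicing-related transcripts (adjusted p = 0.00516 in camera, adjusted p = 0.794 with an estimated correlation) included CLK1 at 17.1 ± 2.78 against 26.9 ± 4.53 and LUC7L at 9.03 ± 0.236 against 10.8 ± 0.523. Ribosomal protein genes (adjusted p = 0.0177 in camera, adjusted p = 0.845 with an estimated correlation) included RPS20 at 17.0 ± 2.09 against 20.8 ± 2.23 and RPL37A at 11.9 ± 1.998 against 14.9 ± 1.42. Y-linked transcripts were near 0 in all APP/PS1 animals and present in 3 of 4 PS1 animals. With the Y-linked level as a covariate, the presynaptic vesicle, immediate early, inhibitory neuron, splicing, matrix and mural lists were no longer called, nor were the ribosomal and pan-neuronal lists, at 0.04 and -0.02 relative to all genes (adjusted p = 0.181 and 0.463 in camera). The splicing list stood at 0.008 relative to all genes there, against -0.05 without the covariate. In total 24 lists were called with this covariate. ASAP3 kept a log2 fold change of -0.87, but its standard error rose from 0.11 to 0.15 and it was not called.

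Leaving out a library ended 12 of these 15 calls at least once, but not the mitochondrially encoded, presynaptic vesicle or histone calls. Without APP/PS1 replicate 3 the adjusted p in camera was 0.0717 for GABA and mural genes, 0.125 for inhibitory markers, 0.0560 for splicing, 0.106 for immediate early, 0.438 for ribosomal, 0.462 for ependymal, 0.629 for pan-neuronal, 0.101 for matrix, 0.0759 for unfolded protein and 0.133 for neuropeptide genes. Without PS1 replicate 3 it was 0.0751 for ependymal, 0.696 for ribosomal, 0.132 for splicing and matrix, 0.159 for excitatory and mural, 0.311 for pan-neuronal, 0.0927 for unfolded protein and 0.0626 for neuropeptide genes. Without PS1 replicate 4 it was 0.174 for ependymal, 0.0828 for inhibitory, 0.0834 for excitatory, 0.106 for mural, 0.0567 for pan-neuronal, 0.197 for matrix and 0.278 for neuropeptide genes. Without PS1 replicate 2 it was 0.130 for immediate early, 0.0693 for ribosomal, 0.0662 for excitatory and 0.119 for unfolded protein genes. Without APP/PS1 replicate 2 it was 0.106 for ependymal, 0.583 for mural, 0.738 for matrix, 0.0759 for unfolded protein and 0.0838 for neuropeptide genes. Without APP/PS1 replicate 1 it was 0.0950 for immediate early genes, and without APP/PS1 replicate 4 it was 0.362 for excitatory and 0.132 for unfolded protein genes. Medians turned below that of all genes for the excitatory list without APP/PS1 replicate 4 (-0.05) and the matrix list without APP/PS1 replicate 2 (-0.01). Without PS1 replicate 1 it was 0.107 for mural, 0.0511 for pan-neuronal and 0.131 for matrix genes. Without WT replicate 1 it was 0.0522 for mural and matrix and 0.0505 for pan-neuronal genes, and without WT replicate 3 it was 0.0554 for mural and matrix and 0.0539 for unfolded protein genes.

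**Figure D4:**
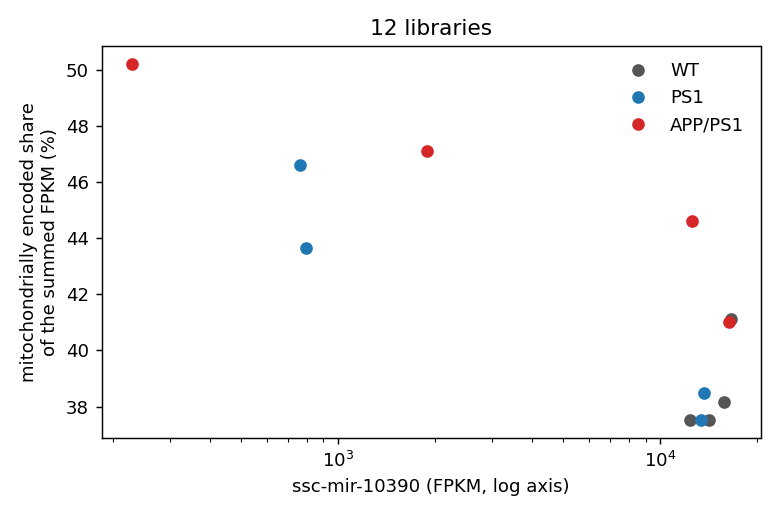
Share of the summed FPKM in mitochondrially encoded genes (%) against the level of ssc-mir-10390 (FPKM, log axis) in each of the 12 libraries, by genotype. The 4 libraries with ssc-mir-10390 at 229 to 1893 are 2 PS1 and 2 APP/PS1 libraries with shares of 43.7% to 50.2%, and no WT library is among them.

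The comparisons against WT share the same 4 control libraries. Both called TUBGCP4 and ENSSSCG00000038107 higher, 2 genes against a mean of 0.010 in simulated unchanged groups and 4.6e-04 for independent lists. When PS1 and APP/PS1 were each set against a different pair of WT libraries, 0 to 2 genes were called in both over 6 splits, and TUBGCP4 was called in both in 3 of them. At an unadjusted p under 0.05, 554 genes moved the same way in both, where simulated unchanged groups gave 0 to 1601 with a mean of 145, independent lists 138 and split controls 103 to 112. The observed count lay within the simulated range. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.51, against a mean of 0.48 in simulated groups (-0.38 to 0.90) and of -0.0015 with split controls (-0.15 to 0.14). The covariance was 0.0172, against a mean of 0.0158 simulated (-0.00636 to 0.0479) and -7.0e-04 with split controls (-0.00918 to 0.00624).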

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

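Tests chosen only after the result was seen were those of the library split and of scaling for mitochondrially encoded genes, both tests for TUBGCP4 and the scaling test for ribosomal protein genes.

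Mitochondrially encoded transcripts were higher in APP/PS1 than in WT. The library split marked by ssc-mir-10390 is argued against as the whole cause, since with the split as a covariate the list's level over the median gene differed by 0.4379 (standard error 0.1199, against 0.6261 without it). Scaling of the deposited values by a factor per library is argued against too, since it moves all genes nearly alike and the difference over the median gene was 0.6261 (standard error 0.1612). RNA quality, reads from nuclear copies of mitochondrial genes and a biological difference between genotypes were not tested and stay open.

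TUBGCP4 was higher in both transgenic genotypes than in WT. A change over the wider chromosomal neighbourhood is argued against by the other 25 tested genes within 1 Mb, with TP53BP1 left out. Their median log2 fold change was -0.03843 in PS1 and -0.1136 in APP/PS1 against WT, and the highest single value was 0.1589. The overlapping gene TP53BP1 rose too, by 0.5084 and 0.343, so a change limited to this pair of genes is not argued against. TUBGCP4 exceeded TP53BP1 by 0.844 and 0.9784 on the log2 scale (standard error up to 0.0849). In PS1 against WT TUBGCP4 went from 6.11 to 17.2 FPKM and TP53BP1 from 11.8 to 17.1. Levels of whole genes do not show where reads lie, and counting by strand is not stated. Reads shared with TP53BP1 are therefore not excluded. A difference in ancestry between transgenic and WT animals, a variant at the gene and an effect of the PSEN1 transgene, which both genotypes carry, were not tested and stay open.

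Ribosomal protein genes were lower in APP/PS1 than in WT. Other genes of like length fell less: 0% of 10000 random lists matched on length had a median as low as -0.2398, where the matched lists' median was -0.1314. Random lists lack the shared variation of ribosomal genes and do not measure the spread between animals. They therefore do not exclude gene length bias. Scaling of the deposited values by a factor per library moves all genes nearly alike, and over the median gene the list differed by -0.1051 (standard error 0.05783). The call held with median-of-ratios scaling and quantile normalization, but not with an estimated correlation (adjusted p = 0.638). With so few animals the difference is not clear of their spread, so scaling stays open. Reads shared with ribosomal pseudogenes and a biological difference were not tested and stay open.

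The 35 splits of each pair of genotypes into 4 and 4 libraries, the real split included, were counted for calls. For genes in APP/PS1 against WT only the real split gave as many (1 of 35), with 5 genes and 0 as the highest of the others. That is the smallest share 35 splits can give, and it is one of several such counts. It argues against chance for the number of genes but does not exclude it. For the number of genes in PS1 against WT chance could not be excluded, as 2 of 35 gave as many as the real 2 genes. The highest other, 13 genes, was the split that follows Y-linked expression and so the sex of the animals. That split is not a draw by chance, and no further split gave as many. The count therefore does not settle chance either way. With the Y-linked level as a covariate, TUBGCP4 and ENSSSCG00000038107 stayed called among 3 genes. For genes in APP/PS1 against PS1 chance could not be excluded, as 4 of 35 gave as many as the real 1, with 7 as the highest other. That split set PS1 replicates 1 and 2 with APP/PS1 replicates 3 and 4 against the rest, and the split that follows ssc-mir-10390 gave 3 genes and 8 lists. ASAP3 kept a similar fold with either covariate. With the ssc-mir-10390 split as a covariate its log2 fold change against PS1 was -0.8707 and called, and against WT it was -0.7663 (standard error 0.1091, before -0.8525 and 0.1057) and not called. With the Y-linked covariate it was -0.87 against PS1, where the call ended as its standard error rose from 0.1057 to 0.1452. For lists chance could not be excluded in PS1 against WT (28 of 35, real 9, highest other 22), in APP/PS1 against WT (13 of 35, real 14, highest other 23) or in APP/PS1 against PS1 (9 of 35, real 15, highest other 19).

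The effect of APP/PS1 against WT on ASAP3 differed from that of PS1 against WT by -0.8707 on the log2 scale, which is the comparison of APP/PS1 with PS1.

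A single library stood apart from the other 3 of its genotype in 22 of 336 tests, where about 17 are expected by chance. The value is the gap to the nearest library as a share of the group's range, on the log2 scale, and levels are in FPKM. In WT replicate 4 RPL8 was at 97.3 against 90.3 to 91.0 (0.8993), ERBB2 at 4.21 against 3.62 to 3.71 (0.8328), PSMC5 at 18.8 against 15.6 to 16.0 (0.8623) and NRGN at 590.0 against 815 to 869 (0.8356), and the mean log2 level of choroid plexus markers was 2.71 against 1.93 to 1.98 (0.9485). In WT replicate 3 CYP4V2 was at 6.5 against 7.19 to 7.31 (0.8616) and VIP at 2.30 against 4.66 to 5.26 (0.8429). In PS1 replicate 2 INPP5F was at 242 against 139 to 153 (0.8308). In PS1 replicate 3 CCNL2 was at 19.1 against 16.1 to 16.3 (0.94), GRIK4 at 5.40 against 7.10 to 7.28 (0.9133) and GABBR2 at 43.7 against 54.0 to 56.1 (0.8473). In PS1 replicate 4 HIST1H1D was at 5.03 against 1.92 to 2.15 (0.8944) and HSPA5 at 77.5 against 88.7 to 91.1 (0.8339). In APP/PS1 replicate 1 CFAP410 was at 3.62 against 3.795 to 3.82 (0.8573), and excitatory neuron markers were at a mean log2 level of 4.87 against 5.27 to 5.33 (0.8517). In APP/PS1 replicate 2 TAGLN was at 15.2 against 3.39 to 4.06 (0.8903), and pericyte and smooth muscle markers were at 3.45 against 2.53 to 2.62 (0.903). In APP/PS1 replicate 3 TMEM14A was at 14.0 against 16.3 to 16.5 (0.9095), NDUFA13 at 4.30 against 4.64 to 4.65 (0.968) and CALB2 at 34.7 against 3.41 to 4.47 (0.8964). In APP/PS1 replicate 4 ND3 was at 14087 against 10376 to 10804 (0.8678), and markers of the hippocampal CA fields were at 3.73 against 3.63 to 3.64 (0.9343).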

How the results depend on the processing

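Alternatives chosen after the data were seen were rescaling to the same sum, both uses of the ssc-mir-10390 split, the fit without the 3 libraries highest in TTR, and limma-voom. TUBGCP4 stayed called in all 31 alternatives in both comparisons against WT (log2 fold change 1.31 to 1.55 and 1.24 to 1.62), and ENSSSCG00000038107 in 31 for PS1 and 30 for APP/PS1. ASAP3 kept its direction in all 31 (-1.06 to -0.72 against WT and -1.06 to -0.79 against PS1) and was not called in 9 and 18. ENSSSCG00000047210 was not called in 17 of 30 and ENSSSCG00000012427 in 25 of 31. Over all named genes, 3140 values kept direction and side of the threshold, 70 lost and 38 gained a call and 4 turned; over called lists 912 kept, 293 lost the call, and 6 lost it with the other direction in camera. Values of lists below are medians of their members. For the changes below the cause was not tested, except where fewer libraries were fitted or the estimated correlation widens the error. Depth limits ENSSSCG00000038107, with 4 to 209 reads per library, and MIR132, with 0 to 7.

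With median-of-ratios scaling 5 lists were called for APP/PS1 against WT and 6 for APP/PS1 against PS1, and APP was at 0.1023 in APP/PS1 against WT. With quantile normalization 5 lists were called for PS1 against WT and 5 for APP/PS1 against WT, with 3 genes, APP was at 0.01625 in APP/PS1 against WT, and the mitochondrially encoded list, whose top ranks this setting makes equal between libraries, was at -0.06907 in PS1 against WT. With limma-voom 5 and 6 lists were called for APP/PS1 against WT and against PS1, APP was at 0.1014 in APP/PS1 against WT, and the neuropeptide list, no longer called in APP/PS1 against WT (adjusted p = 0.983 in camera), had a median of 0.02849 (0.01242 relative to all genes). Rescaled without mitochondrial genes, 7 lists were called for APP/PS1 against PS1. With an estimated correlation 0 lists were called in camera in each comparison, where 0, 2 and 3 had an unadjusted p under 0.05. Rescaling to the same sum, which gives the TPM of the plan, called 923 genes and 25 lists for APP/PS1 against WT. It called 0 genes for APP/PS1 against PS1. PSEN1 was at -0.08954 in APP/PS1 against WT and APP at -0.0503 in APP/PS1 against PS1. Array weights gave 8 genes for PS1 against WT, 285 genes and 25 lists for APP/PS1 against WT and 6 genes in both, with GABRA5 at -0.08282 in APP/PS1 against WT. Robust empirical Bayes gave 3 genes for APP/PS1 against WT. With no filter on low values, and with only the 2 groups compared, limma called 0 genes for APP/PS1 against PS1.

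With the Y-linked covariate 5 lists were called for PS1 against WT, and 0 genes and 24 lists for APP/PS1 against PS1. APP was at 0.007496 in PS1 against WT and -0.1218 in APP/PS1 against PS1, and PSEN1 at -0.007293 in APP/PS1 against WT. In APP/PS1 against PS1 the ribosomal list was at -0.04177 (0.03685 relative to all genes) and the pan-neuronal list at -0.1022 (-0.02357), neither called, and GLRB was at -0.04013. The oligodendrocyte covariate gave 3 genes for APP/PS1 against WT and 9 lists for APP/PS1 against PS1, and the neuronal covariate gave 9 and 0 genes. The covariate for the ssc-mir-10390 split gave 2 genes for APP/PS1 against WT. In the 8 libraries above the split 1 gene was called for APP/PS1 against WT, 1 in both and 0 for APP/PS1 against PS1. There PSEN1 was at -0.1323 in APP/PS1 against WT, APP at -0.1478 and NOTCH3 at 0.02115 in APP/PS1 against PS1, and ATP8 at -0.1227 and the mitochondrially encoded list at -0.03754 (-0.02199 relative to all genes) in PS1 against WT. Without the 3 libraries highest in TTR 5 genes were called for PS1 against WT, 5 in both and 0 for APP/PS1 against PS1, with APP at -0.03022 and the ribosomal list, not called, at -0.03097 in APP/PS1 against PS1 (0.03279 relative to all genes).

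Leaving out each library in turn, genes called ranged from 2 to 6 for PS1 against WT (6 without WT replicate 4) and from 2 to 10 for APP/PS1 against WT. They were 10 without WT replicate 4, 3 without WT replicate 1, PS1 replicate 4 or APP/PS1 replicates 1 or 3, and 2 without WT replicates 2 or 3 or APP/PS1 replicate 2. Genes called for APP/PS1 against PS1 ranged from 0 to 1, with 0 in all cases but that without PS1 replicate 1. Genes called in both ranged from 2 to 5 (5 without WT replicate 4). Lists for APP/PS1 against PS1 ranged from 4 to 17 (4 without APP/PS1 replicate 3 and 7 without PS1 replicate 3). APP ranged from -0.01263 to 0.1171 in APP/PS1 against PS1 (lowest without APP/PS1 replicate 1) and from -0.1125 to 0.01312 in APP/PS1 against WT (highest without APP/PS1 replicate 4). PSEN1 in APP/PS1 against WT ranged from -0.07536 without APP/PS1 replicate 1 to 0.1355, and was -0.04178 without WT replicate 1.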

Other observations

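Further members of fixed lists passed in limma only when adjusted over the list alone. In APP/PS1 against WT the chaperone genes FKBP4 (40.8 against 49.8 FPKM), AHSA1 (41.2 against 50.3) and HSPE1 (48.2 against 59.2) did so, as did the redox genes PRDX3 (56.9 against 69.5), TALDO1 (20.8 against 26.6) and SRXN1 (8.21 against 11.2), and LFNG (16.6 against 22.6) and RFNG (8.05 against 10.2), which modify Notch. The astrocyte gene NDRG2 was at 164.8 in PS1 and 160.4 in APP/PS1 against 208.7 in WT and did so in both comparisons. The linker histone HIST1H1D was at 8.12 in APP/PS1 against 3.25 in WT and the histone variant H2AFZ at 26.1 against 33.3. In APP/PS1 against PS1 DNAJB1 (18.9 against 26.2) and TP53INP1, a target of p53 (3.09 against 4.99), did so, and in PS1 against WT the endothelial gene SOX18 (1.57 against 2.95). With median-of-ratios scaling HIST1H1D passed over its list in both comparisons of APP/PS1, and the others named here did not. The chaperone, redox, Notch, astrocyte, endothelial and p53 lists were not called by camera in any comparison.

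Lists not called numbered 45 in PS1 against WT, 40 in APP/PS1 against WT and 39 in APP/PS1 against PS1, with the lowest adjusted p in camera at 0.0640 for choroid plexus, 0.0553 for inhibitory neuron and 0.0524 for interferon genes. Oligodendrocyte markers had a mean log2 level of 5.39 ± 0.495 in WT, 5.39 ± 0.652 in PS1 and 5.15 ± 0.767 in APP/PS1 (SD, n = 4). Among 4 lists with too few tested members, the blood cell genes HBB and HEMGN averaged 2.41 and 1.97 FPKM in WT, 1.91 and 1.87 in PS1 and 1.11 and 1.75 in APP/PS1. The leukocyte genes NKG7 and JCHAIN ranged from 0.630 to 1.73 and from 0.895 to 1.18 FPKM over the 12 libraries. The first 2 principal components held 27.3% and 20.2% of the variance of the log2 values.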
